A study of Eohaustorius estuarius with 16 samples.

How the data were processed

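Gene expression was measured with one-colour oligonucleotide microarrays in whole bodies of the estuarine amphipod Eohaustorius estuarius, a burrowing crustacean used in sediment toxicity tests. One laboratory of an interlaboratory study, called D in the labels, extracted RNA from whole animals and ran 16 arrays, 8 of solvent controls and 8 of animals held for 10 days on sediment with a nominal 1.6 µg/kg of cyfluthrin, a pyrethroid insecticide. Labelled cRNA carried the dye Cy3. The labels give more than one RNA extraction method for the study and do not say which one this laboratory used. Groups and sample numbers were taken from the sample labels.

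Each array held 15744 spots, of which 15208 were not controls. These spots represented 8507 probes of 60 bases, 6208 of them spotted in 2 places, 2249 in 1 place and 50 in more. The probe table gave a description for 3540 probes and none for 4967. A probe is named here by that description and by the number of the assembled transcript (contig) it was designed from. No genome of the species was used, so probes have no chromosome coordinates here.

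The authors deposited the scanner output of each array, and the intensity values used were the processed signal of each spot, which per the file headers came from Agilent Feature Extraction 10.7.3.1 after background subtraction and detrending within the array. The submitters' processing notes name version 9.1 of that program, so the version is given differently by the 2 sources. The mean signal and the local median background of each spot, also intensities deposited by the authors, served an alternative background correction. The authors also deposited a table of values per probe whose making is not given in the sources used here. From its values, that deposited table holds log2 signals quantile-normalized between arrays and centred on each probe's median. Deposited log2 processed signals treated that way correlated with it at r of 0.99955 to 0.999984 across probes, with slopes near 1 that settle its direction. Its column medians were -0.0049, 0.0042, 0.0070, -0.02, -0.05, 0.11, 0 and -0.0054 for controls 1 to 8 and -0.02, -0.0083, -0.02, -0.05, 0.09, 0.01, -0.01 and 0.11 for cyfluthrin samples 1 to 8. This table was used as an alternative only.

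Control spots and spots marked as outliers by the scanner software were left out (13 to 71 spots per array, 0.0855% to 0.467%), and replicate spots of a probe were averaged. Signals were put on the log2 scale and the 75th percentile of each array was subtracted. A probe was tested when it lay well above background on at least 8 of the 16 arrays, counted over both groups together, which left 6453 probes, 2842 of them described. Of these, 18 lacked a value on 1 array.

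The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The groups were compared with limma (linear model and empirical Bayes, two-sided), with Benjamini-Hochberg adjusted p and a threshold of 0.05. The model had no block in the main comparison. The labels do not say that samples came from separate vessels, so p values measure the spread between these samples, part of which may be technical. The hybridisations filled 4 slides of 4 arrays, each with 2 control and 2 cyfluthrin samples, and slide was tried as a block. All arrays shared 1 scan date.

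Function groups were 22 lists of search terms applied to the probe descriptions. Each list was tested against the other probes with limma's camera at a preset correlation of 0.01, with an adjustment over the 22 lists, and beside it with an estimated correlation and with fry, which asks whether a list's members move one way without reference to other probes. Members past 0.05 were counted after adjustment over all probes and adjusted over the list alone. Genes named in the text follow a rule: the 10 described probes with the largest increase and the 10 with the largest decrease that passed and lay beyond the control median on at least 7 of the 8 cyfluthrin arrays. Among the passing probes of one direction that share a description, only the one with the higher mean signal was eligible, even where another changed more. Open places were filled by the smallest unadjusted p. From every list the member with the smallest p and the one with the highest signal were added. The design, lists, naming rule and most alternative settings were fixed before the data were examined. Chosen later were leaving out control 1 and cyfluthrin 5 together, leaving out probes that rose together, exact permutation of list means, and an estimated correlation with an array or those probes left out.

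The number of probes well above background, the 75th percentile of signal, the correlation between arrays and the scores on 3 principal components were compared between groups by exact two-sided permutation over all relabelings of the 16 arrays, with adjustment over the 3 components. The coefficient of variation of replicate spots was taken per array.

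The fitting steps were tested on data simulated for the comparison of cyfluthrin with control at 6435 probes, in 20 runs. The limma step recovered 5.52% of probes changed 1.5-fold, 35.4% of those changed 2-fold and 82.6% of those changed 4-fold, with a median of 1 and at most 6 false calls. Camera found the antioxidant list, shifted by 1 on the log2 scale, in 20 of the 20 runs. It called 5.24% of unshifted lists with the preset correlation and 0% with the estimated one. That list has an estimated correlation of 0.042, lower than the lists called below, and the shift exceeds their medians. The runs therefore do not give the power for those lists. In other splits of the real arrays, up to 7 lists passed with the preset correlation. The number of arrays limits the precision of every value below.

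Alternatives covered the background correction (normexp with an offset of 50), quantile normalization, centring on the median or on probes detected on all arrays, the authors' deposited table, the filter on dim probes (none, or well above background on all 16 arrays), the variance model, array weights, slide as a fixed or random block, the sample number as a block, a minimum fold change of 1.5 with treat, and leaving out each array in turn. A block for scan date was not run, because the arrays shared one date, and slide as a random block was not run for the lists, because camera takes no random block.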

Results

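Whole-body expression profiles were obtained for 16 samples of Eohaustorius estuarius, 8 from solvent-control sediment and 8 from sediment spiked with cyfluthrin. Between 3435 and 7773 of the 8507 probes lay well above background on an array (40.4% to 91.4%, median 6106.5 probes). The fewest were found in control 1, and cyfluthrin 5 had the fewest of its group. The 75th percentile of processed signal ranged from 137 to 440.1 intensity units, and the coefficient of variation of replicate spots from 4.19% to 8.80%, with a median of 5.41%.

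Cyfluthrin and control animals were compared for transcripts that differed after 10 days on the sediment. In cyfluthrin animals 42 of the 6453 tested probes changed, 32 higher and 10 lower (limma, adjusted p under the threshold of 0.05). A description is given for 24 of them (17 higher, 7 lower). Most of the increase came from 27 probes, 16 of them described, with log2 fold changes of 2.95 to 4.42 and a median of 3.73, or 13.2-fold. These probes, said below to have risen together, are the largest cluster of the 32 higher probes. Clusters were formed by correlation across samples after group means were removed, so varying together is how the set was chosen. The described members include chaperones, glycolytic enzymes, an actin and a protein of the translation machinery. On the other side, 3 probes for heat shock protein 70, a stress-inducible chaperone, fell by 2.63, 2.48 and 2.09 on the log2 scale.

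**Figure D1:**
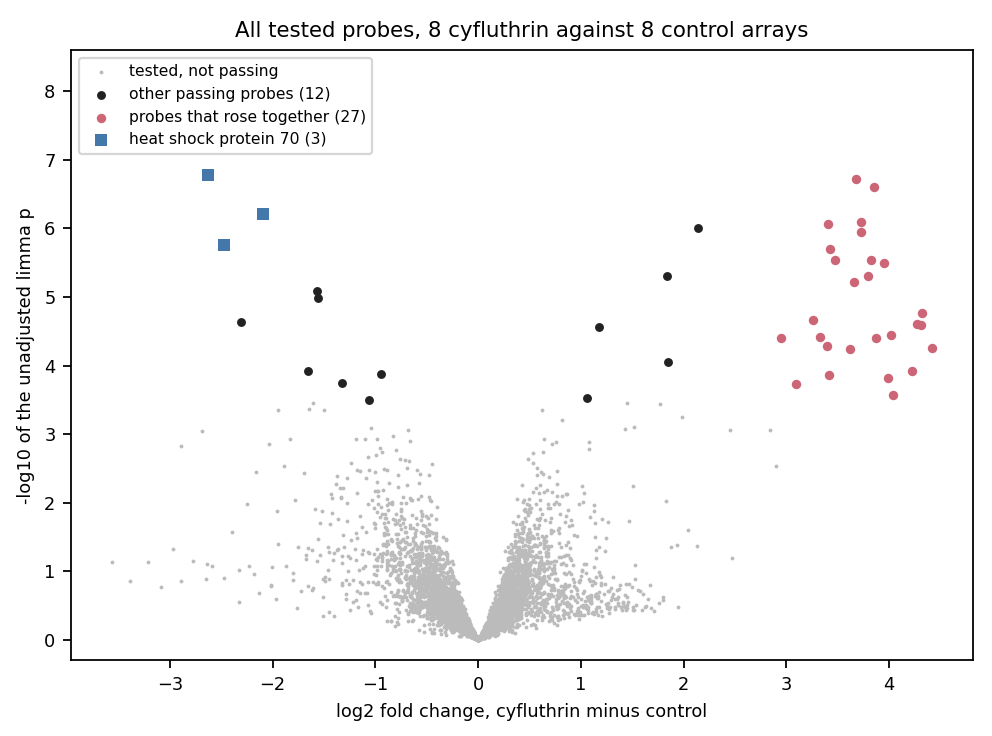
Each point is a tested probe, with the log2 fold change (cyfluthrin minus control) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis, for 8 arrays per group. The 27 probes that rose together (red) lie between 2.95 and 4.42, apart from the other higher probes, of which the largest change is 2.14, and the 3 heat shock protein 70 probes (blue squares) lie between -2.63 and -2.09.

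The largest increases, taking the brightest of the probes that rose under each description, began with rad50. This probe (contig 3691), for a protein of DNA double-strand break repair, rose by 4.32 (standard error 0.73, adjusted p = 0.00582). An SH2 domain-containing protein (contig 4609), of a class that binds phosphorylated tyrosine, rose by 4.22 (0.85, adjusted p = 0.023). Heat shock protein 90 (contig 4879), a chaperone of signalling proteins, rose by 3.85 (0.47, adjusted p = 0.00053), and the p23 co-chaperone (contig 5795), a partner of heat shock protein 90, by 3.79 (0.58, adjusted p = 0.00215). A probe described as myeloid leukemia (contig 7113) rose by 3.73 (0.51, adjusted p = 0.000923), an actin of the cytoskeleton (contig 4390) by 3.72 (0.49, adjusted p = 0.000912) and a translation elongation factor-like protein (contig 4158) by 3.68 (0.44, adjusted p = 0.00053). The set was completed by an alkyl hydroperoxide reductase/thiol-specific antioxidant (contig 7422, 3.66, standard error 0.57, adjusted p = 0.00245), a 60S ribosomal protein (contig 6676, 3.62, 0.68, adjusted p = 0.0118) and a stress-seventy subfamily A protein (contig 4071, 3.47, 0.51, adjusted p = 0.00155).

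These 10 belong to the 27 probes, a set that was recognised only after the values were seen. Its other described members are a second heat shock protein 90 (contig 5659, 3.95), heat shock protein 83-1 (contig 4735, 3.40), glyceraldehyde 3-phosphate (contig 2699, 3.41) and fructose bisphosphate aldolase (contig 6580, 3.33) of glycolysis, a cysteine protease (contig 7908, 3.26) and a probe described as an alveolin of Karlodinium veneficum (contig 4088, 2.95). Alveolins are proteins beneath the membrane of alveolates, and Karlodinium is a dinoflagellate. The mean of the 27 probes was -1.60 ± 1.29 in controls and 2.15 ± 1.15 in cyfluthrin animals (log2 over the 75th percentile, SD, n = 8 each). Control 4 had a mean of 1.12, inside the cyfluthrin range of 0.37 to 3.30, and the next control was at -0.85. All 27 were well above background on each of the 8 cyfluthrin arrays, but only 13 of them on each of the 8 control arrays. The SH2 domain, 60S ribosomal and contig 5659 probes were so on 4 of 8 control arrays and the alveolin probe on 5, so the sizes and order of these changes rest on control values near background. The mean was higher in cyfluthrin on each slide, by 3.47, 4.86, 2.78 and 3.86, and after normexp correction the median change was 2.64, with 24 of the 27 passing.

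Outside this set the largest described increase that passed was in a probe annotated only as protein (contig 5924, 2.14, adjusted p = 0.000912). All 42 changed probes had their direction on each of the 4 slides, which is largely given, since they were chosen for a group difference in these arrays. With slide as a block 38 passed (29 higher, 9 lower), 37 of them among the 42. The SH2 domain probe ended at adjusted p between 0.0508 and 0.0634 without any single one of controls 2, 6, 7 and 8 or cyfluthrin samples 1, 3, 6, 7 and 8 and at 0.0612 when a change above 1.5-fold was required (range over all alternatives 0.00297 to 0.247). The 60S ribosomal probe was 1.28 after normexp correction (adjusted p = 0.0748, range over alternatives 0.000412 to 0.0919).

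**Figure D2:**
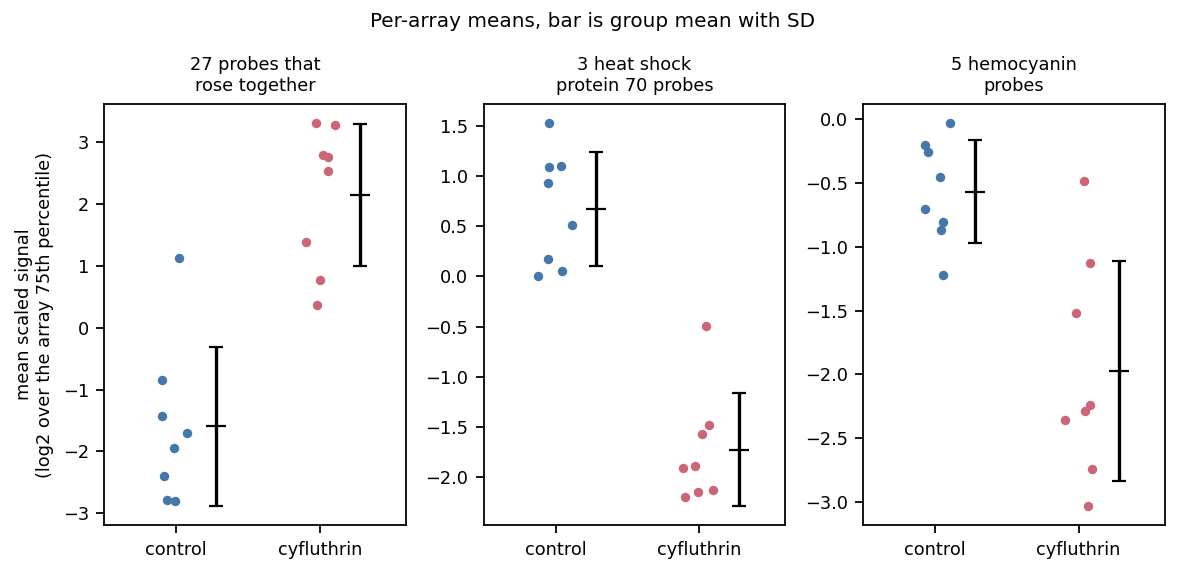
Points are single arrays (8 control, 8 cyfluthrin), bars are the group mean with SD, and the vertical axis is the mean scaled signal, log2 over the array's 75th percentile, of 27, 3 and 5 probes. Control 4 sits at 1.12 among the cyfluthrin values of the 27 probes. The heat shock protein 70 values of the groups stay apart, with the lowest control at 0.0068 and the highest cyfluthrin array at -0.50. Those 3 probes, like the 27, were chosen because they differed. The hemocyanin values overlap, with cyfluthrin 2 at -0.49 and cyfluthrin 4 at -1.13 inside the control range of -1.22 to -0.03.

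The heat shock and chaperone list held 50 tested probes, of which 3 rose and 5 fell with adjustment over all probes, and 3 rose and 7 fell adjusted over the list alone, where heat shock protein 67B2 (contig 982, -0.78) and a heat shock protein 70 (contig 4070) joined. The 3 that rose are the heat shock protein 90 and 83 probes of the set above. The list's search terms missed the p23 co-chaperone (contig 5795) and the stress-seventy protein (contig 4071), chaperones that also rose, so its counts and shift leave them out. Stress-seventy proteins are themselves of the heat shock protein 70 family, so contig 4071 (3.47) went the opposite way to the 3 that fell. Contig 4071, like the 3 list probes that rose, belongs to the set above, whose organism of origin was not tested. Whether it and the 3 that fell are genes of one animal is therefore open. A heat shock 70 cognate (contig 1994) was at 0.25. Of 6 probes described as heat shock protein 70, 3 fell (contig 2087 by 2.63, standard error 0.31, adjusted p = 0.00053; contig 2561 by 2.48, 0.35, adjusted p = 0.00125; contig 2088 by 2.09, 0.27, adjusted p = 0.000912). The other 3 were at -1.24 (contig 4070), -0.09 (contig 2089) and 0.05 (contig 2086). A small heat shock protein (contig 327) fell by 1.56 (0.25, adjusted p = 0.00364) and a further heat shock protein 90 (contig 6339) by 2.31 (0.40, adjusted p = 0.007). The brightest heat shock protein 90 (contig 1253) was at -0.39 (adjusted p = 0.807).

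The mean of the 3 lower heat shock protein 70 probes was 0.67 ± 0.57 in controls and -1.73 ± 0.56 in cyfluthrin animals (SD, n = 8 each), and it was lower on each slide, at -1.96, -1.87, -2.59 and -3.17. As a list, heat shock and chaperone probes did not shift (median 0.02, mean -0.03, camera adjusted p = 0.529). Some members changed (fry, either direction, adjusted p = 1.34e-12), which includes the probes already called and does not test movement both ways. By the same fry test the glycolysis (adjusted p = 7.41e-09), apoptosis (0.000118), digestive (0.00717) and lipid (0.0141) lists passed too. Without the 3 probes of the co-rising set the chaperone list lay lower (median -0.05, adjusted p = 0.0315), a setting chosen after the data were seen that takes out increases only. With an estimated correlation that adjusted p was 0.53. Contig 6339 was well above background on 5 of 8 cyfluthrin arrays, and after normexp correction it was -0.82 (adjusted p = 0.821, range over alternatives 0.0013 to 0.821), where 2 of the 3 heat shock protein 70 probes passed. With a change above 1.5-fold required, contig 6339 was at adjusted p = 0.055 and the small heat shock protein at 0.118 (range over its alternatives 0.000457 to 0.118).

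Other described probes that fell were hexokinase (contig 7050), which phosphorylates glucose at the entry to glycolysis, by 1.57 (standard error 0.25, adjusted p = 0.00307), and copine VIII (contig 1243), of a family of calcium-dependent membrane-binding proteins, by 1.32 (0.28, adjusted p = 0.0308). Copine VIII was well above background on 4 of 8 cyfluthrin arrays, so its change is taken against values near background. The next in order of p did not pass. These were sphingomyelin phosphodiesterase (contig 3482, -1.61, adjusted p = 0.0517), alpha-amylase (contig 833, -1.65), serine protease 42 (contig 4229, -1.94) and a cuticular protein of the RR-1 family (contig 2711, -1.50, adjusted p = 0.0594 for all 3) and cathepsin C (contig 1073, -1.04, adjusted p = 0.0988). Alpha-amylase was well above background on 2 of 8 cyfluthrin arrays and the cuticular protein on 4, so these changes too rest on values near background. Hexokinase was -0.75 after normexp correction (adjusted p = 0.319, range over alternatives 0.00126 to 0.319) and at 0.103 with a change above 1.5-fold required. Copine VIII lost its call under both (-0.37 after normexp, adjusted p = 1 for each), after quantile normalization (0.0652), with the authors' table (0.0661) and without any single one of controls 2, 3, 5 and 8 or cyfluthrin samples 2, 5, 6 and 7 (adjusted p between 0.0506 and 0.082, range over all alternatives 0.0108 to 1). Each of the other 5 passed under some alternatives. Without 1 array, adjusted p was 0.0154 for sphingomyelin phosphodiesterase without cyfluthrin 2 (0.0307 without control 1, 0.0302 without cyfluthrin 1) and 0.0195 for alpha-amylase without cyfluthrin 4 (0.0205 without cyfluthrin 1). It was 0.016 for serine protease 42 without control 4 (0.0371 without cyfluthrin 1) and 0.039 for the cuticular protein without control 2. Sphingomyelin phosphodiesterase also passed with probes required on all 16 arrays (0.0263), with a variance trend (0.0446), array weights (0.0194), slide as a random block (0.0497) and, chosen after the data were seen, without control 1 and cyfluthrin 5 together (0.0413), for a range of 0.0154 to 0.808. Alpha-amylase also passed after quantile normalization (0.0294), with the authors' table (0.0296) and with array weights (0.0451), for a range of 0.0195 to 1. Serine protease 42 also passed after normexp correction (0.0345) and with all 16 arrays required (0.0334), for a range of 0.016 to 0.593. With array weights the cuticular protein was at 0.0163 (range 0.0163 to 1) and cathepsin C at 0.00829 (range 0.00829 to 1), and cathepsin C at 0.0489 without control 1 and cyfluthrin 5.

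The gene lists asked whether whole function groups moved. Hemocyanins, the copper proteins that carry oxygen in crustacean blood, were lower in cyfluthrin animals as a group, with all 5 tested probes below 0 and a median of -0.96. Cuticle and chitin probes and digestive enzymes had medians below 0 (-0.44 and -0.29), and ribosome-related probes had medians slightly above 0 (0.13 and 0.26). These were the 5 of 22 lists past an adjusted p of 0.05 with the preset correlation, and with an estimated correlation only the hemocyanin list passed, depending on single arrays.

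Of the 5 hemocyanin probes 0 passed over all probes and 4 were lower adjusted over the list alone. One member (contig 1872, -0.96) was well above background on 5 control and 4 cyfluthrin arrays. The list fell with the preset correlation (adjusted p = 2.56e-05), with an estimated correlation (adjusted p = 0.024), with fry (adjusted p = 0.00256) and by exact permutation of its mean, a test chosen after the data were seen (adjusted p = 0.0222). With an estimated correlation it lost its call without control 1 (adjusted p = 0.0533), control 2 (0.0546), control 8 (0.0695) or cyfluthrin 8 (0.0828), for a range without 1 array of 0.00359 to 0.0828. The brightest member, a hexameric haemocyanin chain (contig 356), was at -2.69 (adjusted p = 0.0998, 0.0153 without cyfluthrin 2 and 0.017 with array weights, range over alternatives 0.0153 to 0.503). The list mean was -0.57 ± 0.40 in controls and -1.97 ± 0.86 in cyfluthrin animals (SD, n = 8 each). Within slides the difference was -0.97, -2.51, -0.47 and -1.67. With slide as a block and the preset correlation the adjusted p was 1.35e-05.

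The cuticle and chitin list, the structural proteins and enzymes of the exoskeleton, held 55 tested probes, 44 of them below 0. With the preset correlation its adjusted p was 3.11e-05, and with an estimated correlation the adjusted p was 0.566 (unadjusted p = 0.123). No member (0) passed over all probes and 1, the RR-1 cuticular protein of contig 2711, was lower adjusted over the list alone. The brightest member, a cuticle proprotein (contig 1015), was at -0.90 (adjusted p = 0.824), with control values of 2.79 ± 2.32 (SD, n = 8). Within slides the list mean differed by -0.69, -0.90, -0.85 and -0.21. The adjusted p was 4.68e-05 with slide as a block and the preset correlation. With probes required on all 16 arrays the adjusted p was 0.102 (range over alternatives 1.03e-08 to 0.566).

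Of 50 probes caught by search terms for digestive enzymes, such as peptidases, amylases and lipases, 30 were below 0. The terms do not show that these act in gut or hepatopancreas, and 10 are described as cathepsins (median -0.02). The adjusted p of the list was 0.000812 with the preset correlation, and 0.566 with an estimated correlation (unadjusted p = 0.122). Over all probes 0 passed, and 3 were lower adjusted over the list alone, namely alpha-amylase (contig 833), cathepsin C (contig 1073) and trypsin (contig 3407, -2.04). The brightest member was a lipase 1 precursor (contig 3175, -0.76, adjusted p = 0.618). Within slides the list mean differed by -0.42, -0.71, -0.07 and -0.45. With slide as a block and the preset correlation the adjusted p was 0.0019.

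The list named for cytosolic ribosomal proteins held 46 tested probes, of which 39 were in fact described as mitochondrial ribosomal proteins, 2 as ribosome export or assembly proteins and 5 as cytosolic ribosomal proteins. Of the 46, 39 lay above 0 (median 0.13), with an adjusted p of 0.00512 with the preset and 0.566 with an estimated correlation (unadjusted p = 0.132). The 60S ribosomal probe of contig 6676 was the only member that passed, over all probes (1 higher) and adjusted over the list alone (1 higher). The brightest, ribosomal protein L7a (contig 207), was at -0.03. Within slides the mean differed by 0.28, 0.22, 0.32 and 0.17 (adjusted p = 0.00595 with slide as a block and the preset correlation). Without cyfluthrin 5 the median was 0.07 and the adjusted p 0.203 (range over alternatives 0.00212 to 0.566). Without both control 1 and cyfluthrin 5 the median was 0.05 (adjusted p = 0.233).

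The list meant for mitochondrially encoded and ribosomal RNA, a sign of RNA quality, also held other members. Of its 18 tested probes 8 were mitochondrial ribosomal proteins shared with the previous list, 8 were proteins that process ribosomal RNA, 1 was an oxidase assembly protein and 1 was annotated as ribosomal RNA (0.23). The 8 processing proteins had a median of 0.45, and 17 of the 18 probes lay above 0. The adjusted p was 0.00141 with the preset correlation and 0.566 with an estimated correlation (unadjusted p = 0.0899), with 0 members passing over all probes and 0 adjusted over the list alone. The smallest p belonged to the processing protein FCF1 (contig 4315, 0.45, adjusted p = 0.416) and the highest signal to TSR1 (contig 1278, 0.28). Within slides the mean differed by 0.33, 0.11, 0.49 and 0.14. The adjusted p was 0.0019 with slide as a block and the preset correlation. With array weights the adjusted p was 0.0589 (range over alternatives 0.000717 to 0.566).

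**Figure D3:**
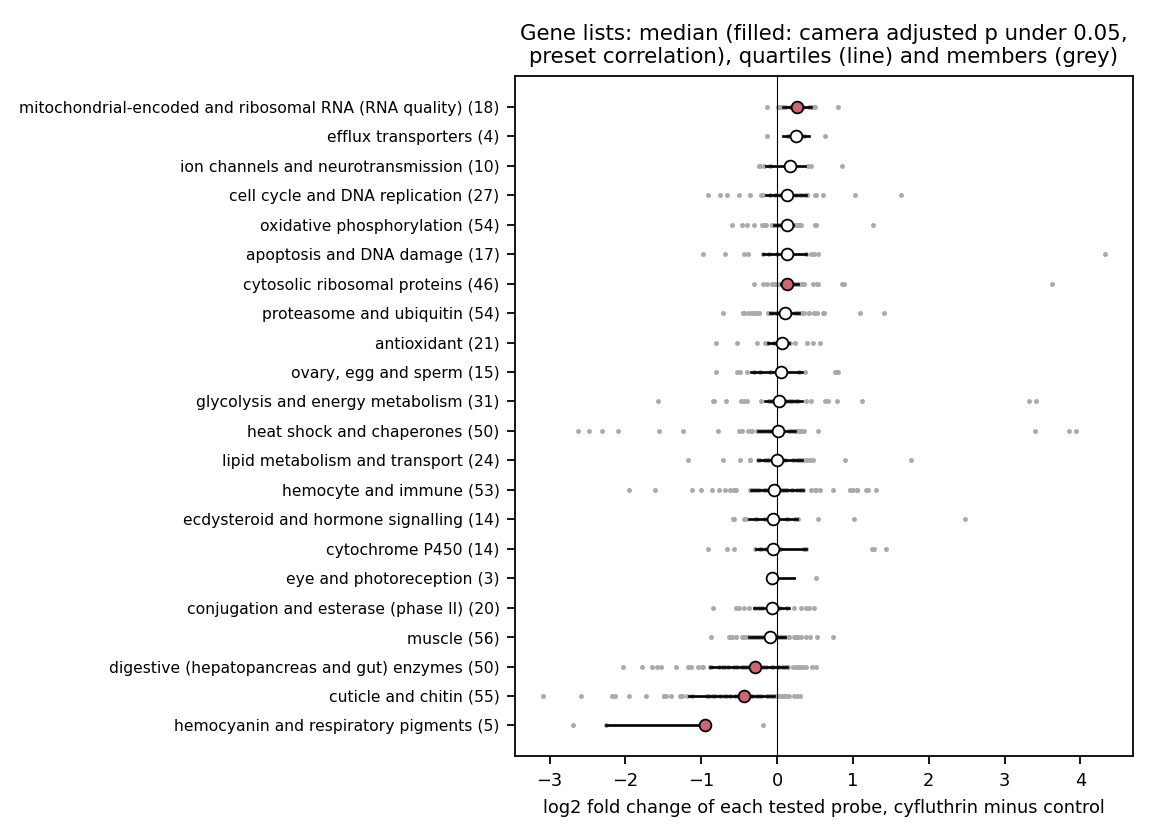
Grey points are the tested probes of each of the 22 gene lists (number of probes in brackets), with the log2 fold change (cyfluthrin minus control) on the horizontal axis, the circle at the median and the line from the lower to the upper quartile. Filled circles mark the 5 lists past an adjusted p of 0.05 with the preset correlation, of which hemocyanin (median -0.96) alone passed with an estimated one on all 16 arrays.

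The remaining lists did not pass with the preset correlation. Of their members named below, thyroid hormone receptor interactor 12, the vitellogenin receptor and retinal degeneration B were well above background on 4 or fewer control arrays and the C-type lectin on 3 cyfluthrin arrays, so their values lie near background. Among lists of detoxification, cytochrome P450 (14 probes, median -0.05, mean 0.13, adjusted p = 0.542) had its smallest p at contig 2965 (-0.65, adjusted p = 0.378) and its highest signal at contig 2661 (-0.15). Conjugation enzymes and esterases (20 probes, median -0.07, adjusted p = 0.727) were led by a carboxylesterase (contig 4751, -0.85, adjusted p = 0.604) and a microsomal glutathione S-transferase 3 (contig 464, -0.37). The efflux transporter list (4 probes, 0.25, adjusted p = 0.542) was led by ATP-binding cassette proteins of subfamily F (contig 673, 0.36, and contig 2491, 0.14). These matched the search term ATP-binding cassette, which does not show that they carry out efflux. The antioxidant list (21 probes, 0.06, adjusted p = 0.727) had 0 members passing over all probes and 1 lower adjusted over the list alone, peroxiredoxin 6 (contig 1025, -0.80, adjusted p = 0.153). Its search terms missed the alkyl hydroperoxide reductase/thiol-specific antioxidant of contig 7422, which rose. Proteasome and ubiquitin probes (54, median 0.10, adjusted p = 0.265) included the conjugating enzyme E2-25kD (contig 3343, 0.61, adjusted p = 0.421) and the proteasome maturation protein (contig 2862, 0.16).

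Pyrethroids act on sodium channels of nerve cells. Ion channel and neurotransmission probes numbered 10 (median 0.17, adjusted p = 0.529), with an inward rectifier potassium channel (contig 5332) at 0.85 (adjusted p = 0.682) and an acetylcholinesterase precursor (contig 1513) at -0.17 (adjusted p = 0.892). Muscle probes (56, median -0.10, adjusted p = 0.207) included sarcoplasmic calcium-binding protein (contig 6837, -0.46, adjusted p = 0.46) and a titin-like protein (contig 7449, -0.59). The list passed without cyfluthrin 8 with the preset correlation (adjusted p = 0.0352), but adjusted p was 0.562 with an estimated correlation. Hemocyte and immune probes (53, median -0.04, adjusted p = 0.542) included a C-type lectin (contig 5680, -1.96, adjusted p = 0.43) and a glucan-binding protein (contig 191, -0.62). Ovary, egg and sperm probes (15, median 0.05, adjusted p = 0.703) included a vitellogenin receptor (contig 6519, 0.76, adjusted p = 0.748) and missing oocyte (contig 3002, -0.30). The eye list (3 probes, median -0.06, mean 0.11, adjusted p = 0.852) included retinal degeneration B, a phosphatidylinositol transfer protein of fly photoreceptors (contig 7877, 0.51). It also held cat eye syndrome critical region protein 2 (contig 8540, -0.12), which is no eye gene. Ecdysteroid and hormone probes (14, median -0.05, mean 0.15, adjusted p = 0.789) included thyroid hormone receptor interactor 12, caught by its name (contig 2997, 1.01, adjusted p = 0.31, and 0.0231 with array weights). They also included a juvenile hormone-inducible protein (contig 7776, 2.47, adjusted p = 0.659). Its change rests on controls 3 and 6 of slide 1, at -5.79 and -5.10, where the other controls were at 1.05 to 3.07. Within slides it differed by 8.82, -0.22, 1.68 and -0.39.

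Oxidative phosphorylation (54 probes, median 0.13, adjusted p = 0.213) included NADH dehydrogenase (contig 2515, 0.51, adjusted p = 0.44) and an ATP synthase subunit (contig 530, -0.07), and passed without control 8 with the preset correlation (adjusted p = 0.019), but adjusted p was 0.69 with an estimated correlation. In glycolysis and energy metabolism (31 probes, median 0.03, adjusted p = 0.542), 2 probes rose and 1 fell, over all probes and adjusted over the list alone. These were glyceraldehyde 3-phosphate (contig 2699, 3.41, adjusted p = 0.000912), aldolase (3.33) and hexokinase (-1.57). Lactate dehydrogenase (contig 498) was at -0.08. Lipid metabolism and transport (24 probes, median -0.0075, mean 0.06, adjusted p = 0.881) had 0 members passing over all probes and 1 higher adjusted over the list alone. This was the very low-density lipoprotein receptor (contig 3297, 1.77, adjusted p = 0.0521, and 0.0161 without control 2, 0.0487 without cyfluthrin 5 or 0.0144 without cyfluthrin 8). It also passed with a variance trend (0.0489), array weights (0.0122) and slide as a random block (0.0497). Apolipoprotein D (contig 2274) was at -0.24. Cell cycle and DNA replication (27 probes, median 0.14, adjusted p = 0.542) included MAD2 of the mitotic checkpoint (contig 4359, 1.03, adjusted p = 0.348) and linker histone H1M (contig 5070, -0.50). Apoptosis and DNA damage (17 probes, median 0.13, adjusted p = 0.396) had 1 probe higher over all probes, rad50, and 2 higher and 1 lower adjusted over the list alone, the others being programmed cell death protein 11 (contig 2443, 0.54) and a programmed cell death protein (contig 4148, -0.98). DNA repair protein XRCC1 (contig 4482) was at -0.39. After normexp correction the medians of the antioxidant, heat shock, proteasome, ion channel, ovary and glycolysis lists lay below 0, and the lipid median lay above 0 after quantile normalization (0.03). The median of all tested probes also moved, from 0.0066 to -0.06 with normexp and to 0.03 with quantile normalization. Camera, which sets a list against the other probes, kept the direction of each of these lists there.

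The arrays as a whole were compared to learn whether treatment set the overall signal. Probes well above background numbered 6044 ± 1276 in controls and 6307 ± 965 in cyfluthrin animals (SD, n = 8 each), a difference of 263.6 (exact permutation p = 0.660). The 75th percentile of signal was 271 ± 87.5 and 281 ± 82.5 intensity units (exact permutation p = 0.823). Pairs of arrays correlated at 0.642 to 0.964 over the tested probes, and the mean was 0.857 within and 0.847 between groups (exact permutation p = 0.135, and 0.0477 without cyfluthrin 8). The first 3 principal components held 29.2%, 24.0% and 11.7% of the variance. Group scores differed by -24.6 (cyfluthrin minus control) on the first (exact permutation, adjusted p = 0.301), -2.56 on the second (adjusted p = 0.895) and -25.4 on the third (unadjusted p = 0.0337, adjusted p = 0.101). Averaged within slides, the third differed by -25.4 with an adjusted p of 0.162, and it passed without control 3 (adjusted p = 0.0256), control 6 (0.0177) or cyfluthrin 4 (0.0266).

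**Figure D4:**
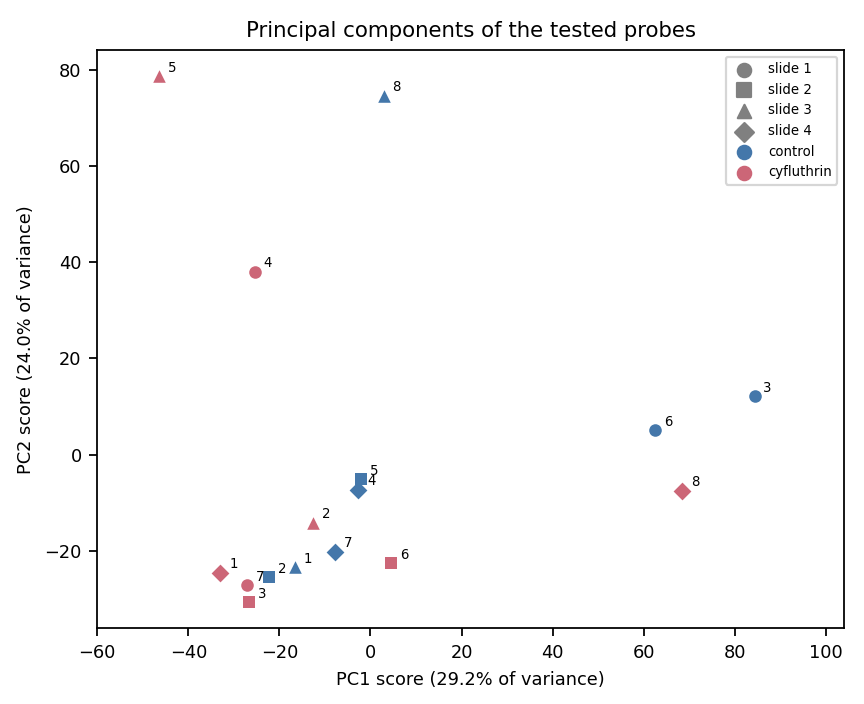
Each array is placed by its scores on the first (29.2% of variance) and second (24.0%) principal components of the tested probes, with the sample number beside it, colour for group (blue control, red cyfluthrin) and shape for slide. Controls 3 and 6 and cyfluthrin 8 lie at scores of 62.5 to 84.4 on the first component, control 8 and cyfluthrin 5 at 74.7 and 78.7 on the second, and the groups overlap on both.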

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

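Of the tests in this part, those of another organism, of the scaling of the arrays and of slide were chosen after the result was seen. In 176 groups of 8 values, 27 had 1 sample that stood far from the other 7, and chance alone gives this in about 5% of groups.

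Control 4 was the highest control in 25 of the 27 probes that rose together, and in 6 named ones it stood far from the other controls. Its values there were 1.88 for heat shock protein 90 (next control -0.25), 1.07 for the p23 co-chaperone (next -1.47), -0.045 for actin (next -2.30), 2.56 for the elongation factor-like protein (next 0.55), 3.26 for the stress-seventy protein (next 1.08) and 1.64 for glyceraldehyde 3-phosphate (next -0.15). The set of 27 was itself picked from the probes that changed, and for varying together. A sample that stands out in many of them at once is therefore partly built in.

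Of the 351 probe pairs of the set 0% share a stretch of 20 bases, which argues only against one repeated probe sequence. The probes were designed from different contigs, so this was likely beforehand. Probes for different parts of one transcript would share no bases either. After quantile normalization the median was 3.81, which was likely beforehand for probes chosen for large changes under another scaling. Group means of the 75th percentile before scaling were 271 (control) and 281 (cyfluthrin) intensity units. These are too close for scaling alone to give a median change of 13.2-fold. An offset of a whole slide was already balanced by the design, with 2 samples of each group per slide. The smallest within-slide difference was 2.78, in probes chosen for a large difference. One hypothesis is RNA of another organism in or on the animals, which may carry its own actin, chaperones and glycolytic enzymes. The other 68 tested probes found by search terms for such functions had a median of 0.12, but most are mitochondrial ribosomal proteins, and taking out those that rose nearly fixes a value near 0, so this does not favour any explanation. The set holds a probe described as an alveolin of the dinoflagellate Karlodinium veneficum (contig 4088), but that description alone does not give the origin of the set. RNA of another organism, a response to exposure, vessels that are not named in the labels and gene copies of the animal cannot be told apart, since no sequence of another organism was compared.

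Among the chaperones that fell, control 5 was at -3.94 for the heat shock protein 90 of contig 6339 (next control -2.24). Cyfluthrin 6 was at -0.22 for the heat shock protein 70 of contig 2087 (next -1.49), the highest of its group.

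Cyfluthrin 4 stood high in the cuticle and chitin list, with a mean of -0.30 (next -1.71), and in the cuticle proprotein of contig 1015, at 5.17 (next 2.36). Control 3 was low in the ecdysteroid and hormone list at -1.94 (next -1.46), in the cell cycle list at -1.14 (next -0.68) and in MAD2 at -5.24 (next -3.64).

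Control 8 was at 74.7 on the second principal component (next 12.1), at 0.085 for the carboxylesterase of contig 4751 (next 0.96), at 2.97 for the ubiquitin-conjugating enzyme (next 2.10) and at 3.67 for missing oocyte (next 5.42). Cyfluthrin 5 was at 2.13 for missing oocyte (next 4.44), at 0.70 for XRCC1 (next 2.11) and at 0.34 for the list of ribosomal RNA and its processing (next -0.16).

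Cyfluthrin 8 was at 68.4 on the first principal component (next 4.50), at -2.26 in the cytochrome P450 list (next -1.21), at -3.55 for the potassium channel of contig 5332 (next -2.05) and at 4.23 for lactate dehydrogenase (next 3.39). Cyfluthrin 7 was at -2.57 for sarcoplasmic calcium-binding protein (next -1.89). Control 1 was at 1.62 for the lipase 1 precursor (next 2.96), and its replicate spots had the highest coefficient of variation, 8.80% (next control 6.11%).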

How the results depend on the processing

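Leaving out both control 1 and cyfluthrin 5, leaving out the 27 probes that rose together, the exact permutation of list means, and an estimated correlation with arrays or probes left out were chosen after the data were seen. Over all alternatives but this last, named genes kept direction and side of the threshold in 1641 cases, lost their call in 34, gained one in 31 and turned in 12. The 5 lists past the threshold kept both in 140 cases and lost their call in 15. The other 17 lists kept both in 500, gained a call in 5 and turned in 19, spread over 8 lists, with adjusted p of 0.58 or more. The 42 changed probes became 93 with array weights (62 higher, 31 lower), 27 when a change above 1.5-fold was required (24 higher, 3 lower), 30 to 46 under the other scalings, filters, variance models and slide blocks, 58 without both arrays, and 31 to 49 without any 1 array. With the sample number as a block they were 19 (13 higher, 6 lower), and these numbers do not pair the samples (r from -0.33 to 0.37, 1 of 8 best with its own number). The 5 lists became 3 with probes required on all 16 arrays, 3 with array weights, 1 with an estimated correlation, which by construction widens the error of lists whose members vary together (0 of them without control 8 or without cyfluthrin 8, 1 without the co-rising probes), 3 without both arrays, 3 by exact permutation (hemocyanin, and apoptosis and glycolysis, which hold co-rising probes), 6 without the co-rising probes and 4 to 6 without any 1 array. The difference in probes above background was -224.5 against negative controls plus 3 SD, and -109 (without control 1) to 511 without 1 array. That of the 75th percentile was -9.64 (without cyfluthrin 4; -9.53 without control 1) to 33.7. Agreement differed by 0.00537 to 0.0152. The second component's difference was 3.34 after quantile normalization, -18.2 (adjusted p = 0.0284, range 0.0284 to 0.96) with all 16 arrays required, where its loadings correlate with the original ones at only 0.321, and -15.9 to 27.2 without 1 array (14.0 without control 8, 2.51 without cyfluthrin 6). The third's was -13.0 (adjusted p = 0.0427) with all 16 required (loadings correlated at 0.7997) and -31.6 to -6.31 without 1 array. Without 1 array, genes near 0 changed sign: missing oocyte -0.56 to 0.13 (0.041 with array weights, 0.18 without both arrays), ribosomal protein L7a -0.21 to 0.11, acetylcholinesterase -0.32 to 0.0041, ATP synthase -0.15 to 0.0056 and lactate dehydrogenase -0.21 to 0.0072. The cause was not tested. Normexp correction ended the calls of hexokinase, copine VIII, contig 6339 and the 60S ribosomal probe. Scan date was not run as a block, since there was 1 date, nor slide as a random block for lists.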

Other observations

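The tests of the whole chaperone class, of slide and of moult stage, and the spread by group, in this part were chosen after the result was seen, and the bounds for slide and for brightness were tightened after their values were seen.

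Exoskeleton genes varied between arrays. Of the 55 cuticle and chitin probes, 20 lay in the top 5% of loadings of the first principal component, 16 of the second and 23 of the third, where 2.75 would fall by chance. The sign of each component was set by the sum of this list's loadings, so that it lies at the top and not the bottom is given. The bottom 5% held 0, 0 and 1 of these probes. At the other end of the first component lay 11 of 53 hemocyte and immune probes (2.65 by chance) and 6 of 15 ovary, egg and sperm probes (0.75 by chance). The third component also held 12 of 50 digestive enzymes (2.5 by chance) and 10 of 53 immune probes (2.65 by chance) at its top. The mean of the ovary list had an SD of 0.740 between arrays of one group, against 0.815 for the cuticle list and 0.114 for glycolysis.

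A hypothesis for the spread of the cuticle list is that animals differed in moult stage, since cuticle genes may switch together in the moult cycle. The SD of the list mean within groups, 0.815, lay at percentile 100 of 10000 random lists of like size and level (highest 0.334), which other causes that act on cuticle genes together would also give. The SD was 0.9502 among controls and 0.654 among cyfluthrin arrays, where it rests on cyfluthrin 4: without that array it was 0.238, under the 99th percentile of random lists (0.275). Slide means held 20.3% of the variance (permutation p = 0.455, 10.9% to 34.4% without 1 array). The list mean correlated with the number of probes above background at 0.282 (permutation p = 0.347). That correlation was 0.171 to 0.418 without 1 array and 0.098 without the 2 arrays farthest in number of probes. With 16 arrays neither slide nor brightness can be excluded, and moult stage is not given in the labels.

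For the 3 heat shock protein 70 probes that fell, 0% of their 3 pairs share a stretch of 20 bases, which argues against one repeated probe sequence, though they may still report different parts of one transcript. The other 44 chaperone probes outside the co-rising set had a median of 0.017 (quartiles -0.23 to 0.21), against a fall of the whole class relative to other probes. A loss of yield common to all probes is removed by the scaling and was not tested. The slide with the difference nearest to 0 had -1.87, in probes chosen for a large difference, and the balance of groups on each slide already cancels a whole-slide offset. As a hypothesis, the exposure lowered these transcripts, and a difference between vessels, which the labels do not give, stays open.

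Chance is an unlikely source of the number of changed probes. Of 100 splits of the 16 arrays, only 1, the real one, gave as many as 42, and the highest of the others gave 27. These were a part of all possible splits, and splits of arrays do not test for vessels, so chance is not strictly excluded. For the number of shifted lists chance stays open, since 11 of 100 splits gave 5 or more and the highest of the others gave 7.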
